A study of Homo sapiens with 96 samples.

How the data were processed

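Messenger RNA of HepG2 cells had been measured on 96 Affymetrix HT HG-U133+ PM arrays, with 100 ng of RNA per labelling reaction according to the labels. The deposited values were on a log2 scale, made by the submitters with the RMA method (background correction, quantile normalization and summary by probe set), whose software version was not given. The table held 54715 probe sets and 96 arrays, with values from 1.2 to 13.81 and array medians from 2.552 to 2.649. No further normalization was applied. The arrays fell into 26 groups by drug, addition and time as the labels give them, 18 groups of 4 and 8 groups of 3, and that number limits the precision.

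Probe sets were assigned by the gene symbol in the platform table. Of them 40920 carried 1 symbol, 864 several and 12931 none, and only those with 1 symbol were used. No symbol needed an update (0), and 40858 matched an Entrez identifier in the reference. A gene was represented by its probe set with the highest mean over the 96 arrays, which gave 19774 genes, 10550 of them with more than 1 probe set. Some genes of interest were not analysed here and are not reported.

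Differences were tested with limma 3.58.1 in R 4.3.3, and files were read with the package data.table, version 1.17.8. A single fit over the 96 arrays had a mean for each group, comparisons were contrasts of these means, and the variance prior followed mean expression. A gene was called, and said to rise or fall, when its Benjamini-Hochberg adjusted p over all genes was below 0.05 and its change was at least 1.5-fold. The 25 planned comparisons, the tests, the gene lists, the rule for naming genes and most alternatives were chosen before the data were examined. They set each drug against DMSO at 14 h, TNF for 1 h or 6 h against its control in DMSO and after each drug, the response to TNF for 6 h after a drug against that in DMSO, and BSA for 6 h against no addition after 3 drugs. The 5 comparisons of the response to TNF for 1 h were added after the data had been seen. For nefazodone, which had no group without addition, the BSA 6 h arrays stood for the drug alone. The methotrexate control joined 2 arrays labelled 14 h, whose titles also name 6 h, with 1 labelled BSA 6 h. The DMSO controls had no BSA.

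Genes were named by a fixed rule. For each drug against DMSO and for TNF in DMSO these were the 10 called genes with the largest rise and the 10 with the largest fall, and for other comparisons the 5 and 5. Their replicates could not overlap between the groups (not asked of the differences in response), and their mean had to exceed the median of all gene values, 3.603, in the higher group. Up to 4 called members of each gene list per comparison and 22 fixed genes, such as NFKBIA, DDIT3, CYP1A1 and ALB, were named as well.

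The 27 gene lists covered NF-kB targets, feedback genes of TNF and NF-kB signalling, acute phase proteins, immediate early genes, ATF4 and CHOP targets, ER chaperones, NRF2 targets, p53 targets, cholesterol synthesis, fatty acid synthesis, PPARA targets, AhR targets, PXR and CAR related drug metabolism, hepatocyte products, bile acids, G1/S and DNA replication, G2/M and mitosis, folate and nucleotide synthesis, heat shock proteins, metallothioneins, TNF receptor death signalling, interferon stimulated genes, the respiratory chain, glycolysis and hypoxia, ribosomal proteins, ribosome biogenesis, and autophagy and lysosome. They were written from general knowledge, and some genes are on more than 1 list. Each list was tested against the other genes with camera in limma, with a preset correlation between genes of 0.01, and the p-values were adjusted over the 27 lists of a comparison. Of 675 list tests 212 passed with the preset correlation, 80 with a correlation estimated from the data, and 80 with both. Median, mean and test were not all of the same sign in 93 tests, of which 0 passed.

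The method was tested on simulated data in which known genes were changed. For diclofenac against DMSO it recovered 47.8% of genes changed 1.5-fold and 100% of those changed 2-fold or 4-fold, with 1 false call, and for nefazodone 38.8%, 100% and 100% with 3. For TNF for 6 h with methotrexate, with 3 arrays a group, the shares were 46.3%, 95.5% and 100% with 2 false calls. For the difference in the TNF response with diclofenac they were 29.9%, 86.6% and 100% with 5 false calls, and with nefazodone 35.8%, 85.1% and 100% with 1. The simulated genes varied independently, and only genes above the median of all gene values were changed. These figures therefore do not cover dim genes or structure among the real arrays.

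Alternatives changed a single choice each. They were a filter that kept 15399 genes above the array median on at least 3 arrays and removed 4375, quantile normalization of the deposited values, the mean of all of a gene's probe sets, a variance prior without the trend, only the groups of a comparison in the fit, the replicate number as a block, other control arrays of the same drug, and each array left out in turn. Arrays with TNF for 6 h on both sides, the ketoconazole arrays numbered 4 left out and the single methotrexate array labelled BSA 6 h were added after the data had been seen. The replicate numbers were checked for pairing on residuals from the group means. Arrays of different groups with the same number had a median correlation across genes of 0.154, against -0.0581 with different numbers, and in 22 of 30 comparisons every such pair exceeded 0.1. No pair of arrays correlated above 0.9976 across genes, and the lowest mean correlation of an array with its own group was 0.9895. Results for comparisons with other splits of the arrays are given with the results they belong to.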

Results

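The study measured messenger RNA in HepG2 cells, a human liver cancer cell line, on 96 arrays of a single platform. Cells received the solvent DMSO or one of 5 drugs, and some groups then received tumour necrosis factor (TNF), an inflammatory cytokine, or bovine serum albumin (BSA), the carrier protein used as its control. The drugs were diclofenac (an anti-inflammatory), carbamazepine (an anticonvulsant), ketoconazole (an antifungal), methotrexate (an antifolate) and nefazodone (an antidepressant). Diclofenac, carbamazepine and ketoconazole each had 5 groups of 4 arrays, namely drug for 14 h, and drug for 8 h followed by BSA for 1 h, BSA for 6 h, TNF for 1 h or TNF for 6 h. DMSO had 3 groups of 4 arrays (14 h, TNF 1 h and TNF 6 h) and no BSA group. Methotrexate and nefazodone each had 4 groups of 3 arrays. Apart from 2 methotrexate arrays, whose titles give no such words, the titles of replicate arrays all read biological replicate 1, and nothing in the labels states that they came from separate cultures, so the p-values measure only the spread between these arrays. Doses were not in the labels. Values were log2 signals from 1.2 to 13.81, array medians lay between 2.552 and 2.649, and the number of arrays per group limits the precision.

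The first set of comparisons asked what each drug did on its own, against the 4 DMSO arrays at 14 h. A gene was called when its adjusted p from limma passed the threshold and its change was at least 1.5-fold. Among 19774 genes, 777 rose and 644 fell with diclofenac, 264 rose and 184 fell with carbamazepine, and 1526 rose and 2145 fell with ketoconazole. With methotrexate 691 rose and 682 fell, and with nefazodone 1285 rose and 1868 fell. Genes that changed at least 2-fold numbered 224 up and 113 down with diclofenac, 41 and 11 with carbamazepine, 719 and 711 with ketoconazole, 229 and 117 with methotrexate, and 478 and 624 with nefazodone. Changes below are log2 differences of group means with their SE.

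**Figure D1:**
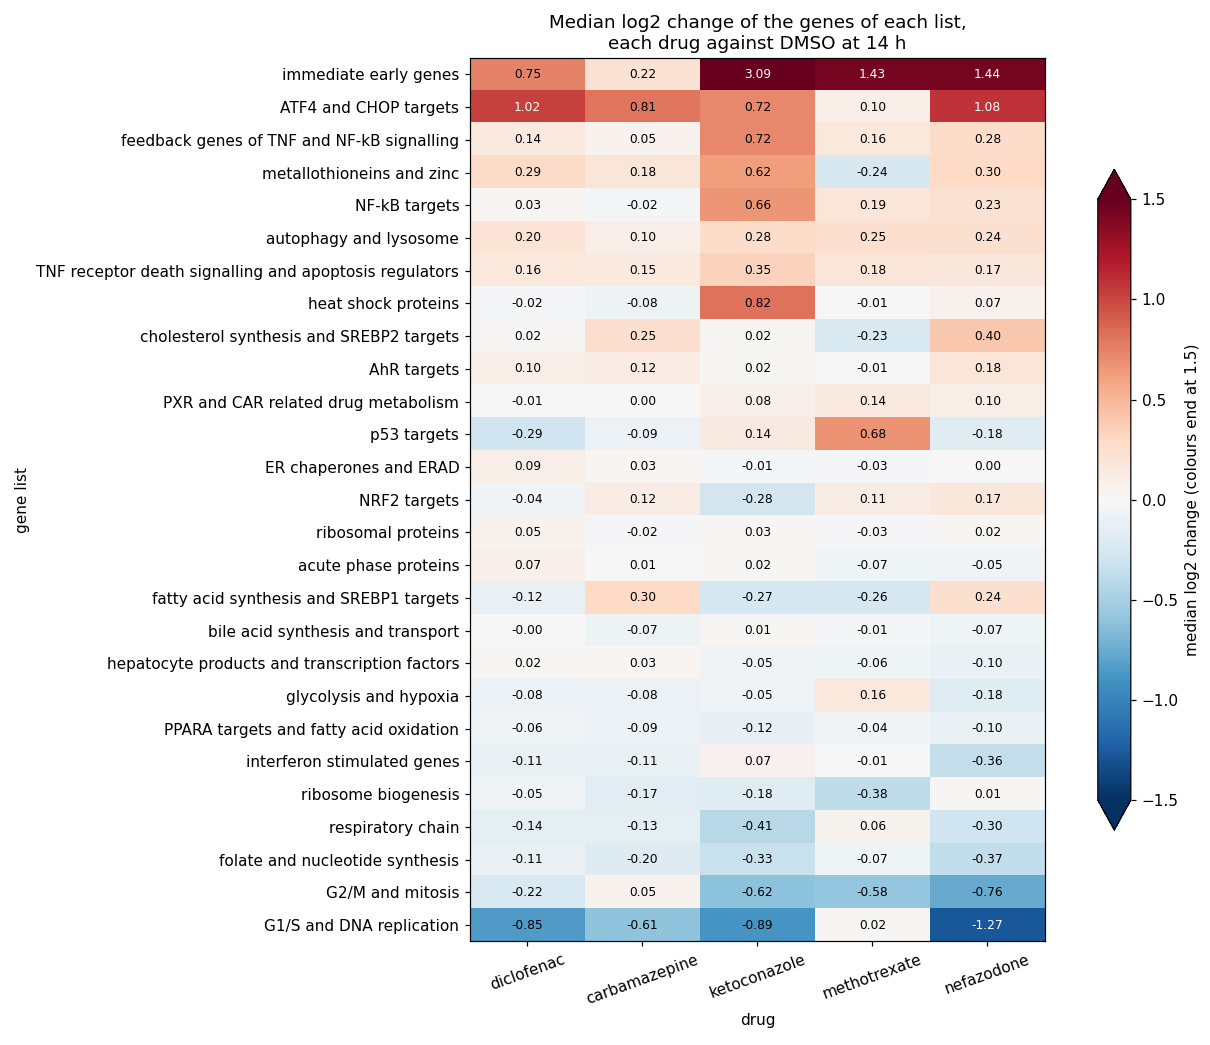
Each cell gives the median log2 change of the measured genes of a list (vertical axis) for a drug against DMSO at 14 h (horizontal axis), and its colour shows the same value. The immediate early genes had their highest median, 3.09, with ketoconazole, and the G1/S and DNA replication genes their lowest, -1.27, with nefazodone.

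Diclofenac raised targets of the stress transcription factors ATF4 and CHOP and lowered genes of DNA replication (4 arrays against 4). DDIT3 (Entrez 1649), which codes for CHOP, rose by 3.03 ± 0.13, its partner ATF3 by 2.40 ± 0.14 and DDIT4, an inhibitor of mTORC1, by 2.39 ± 0.14. EGR1 (Entrez 1958), an immediate early transcription factor, rose by 3.27 ± 0.17, and SLC44A2, a choline transporter-like protein, by 3.10 ± 0.20. FAM111B had the largest fall, with a change of -2.75 ± 0.21, and UHRF1, a maintenance factor of DNA methylation, changed by -1.83 ± 0.10.

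Of 29 ATF4 and CHOP targets, 20 rose and 9 were not called (median 1.02, adjusted p = 8.4e-39, and adjusted p = 1.2e-09 with an estimated correlation). Among them TRIB3 rose by 1.72 ± 0.10 and the cystine transporter gene SLC7A11 by 1.59 ± 0.15. Of 23 immediate early genes, 12 rose and 11 were not called (median 0.75, adjusted p = 6.3e-17, and adjusted p = 0.00012 with an estimated correlation), with DUSP1, a phosphatase of MAP kinases, up by 2.13 ± 0.12. Genes of G1/S and DNA replication went the other way, as 21 of 29 fell and 8 were not called (median -0.85, adjusted p = 4.5e-38, and adjusted p = 5.9e-05 with an estimated correlation). GINS2 changed by -1.41 ± 0.09, the flap endonuclease gene FEN1 by -1.28 ± 0.10 and the helicase gene MCM2 by -1.25 ± 0.10. Of 26 p53 targets, 9 fell, 3 rose and 14 were not called (median -0.29, adjusted p = 0.0041, and adjusted p = 0.28 with an estimated correlation). PHLDA3 changed by -1.68 ± 0.18, and the risers were BBC3, PLK3 and TNFRSF10B. Of 27 autophagy and lysosome genes, 6 rose and 21 were not called (adjusted p = 0.0001, and adjusted p = 0.11 with an estimated correlation), with MAP1LC3B up by 1.22 ± 0.09. The counts adjusted over the list alone were the same for these 5 lists.

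The albumin gene ALB differed by -0.02 ± 0.04 with diclofenac, the chaperone gene HSPA5 by 0.07 ± 0.07 and NQO1, a target of NRF2, by -0.04 ± 0.07, none of them called. CYP1A1 (Entrez 1543), a cytochrome P450 gene under control of the aryl hydrocarbon receptor (AhR), rose by 1.74 ± 0.35, the single AhR target of 8 that was called (list adjusted p = 0.44, and 1 riser adjusted over the list alone). With the diclofenac BSA 6 h arrays in place of the 14 h arrays its change was -0.39.

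Carbamazepine raised targets of ATF4 and CHOP and lowered genes of DNA replication (4 arrays against 4). IL21R rose by 2.78 ± 0.22, DDIT3 by 2.13 ± 0.13, ANGPTL8, a regulator of lipoprotein lipase, by 2.04 ± 0.21, and DDIT4 by 1.67 ± 0.14. The actin gene ACTA1 had the largest fall, -2.19 ± 0.21, and TAGLN, which codes for an actin-binding protein, changed by -1.72 ± 0.25. ALB differed by -0.00 ± 0.04, CYP3A4 by 0.21 ± 0.11 and NQO1 by 0.17 ± 0.07, none of them called.

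With carbamazepine 18 of 29 ATF4 and CHOP targets rose and 11 were not called (median 0.81, adjusted p = 2.1e-56, and adjusted p = 1.2e-12 with an estimated correlation), among them SLC7A11 by 1.51 ± 0.15 and TRIB3 by 1.30 ± 0.10. Of 29 G1/S and DNA replication genes, 15 fell and 14 were not called (median -0.61, adjusted p = 1.3e-40, and adjusted p = 3.1e-05 with an estimated correlation), with MCM5 at -0.97 ± 0.10 and UHRF1 at -0.95 ± 0.10. Genes of fatty acid synthesis lay higher as a group (median 0.30, adjusted p = 1.5e-06, and adjusted p = 0.019 with an estimated correlation), with ACSS2 and PNPLA3 the 2 of 14 that rose and 12 not called. The call of PNPLA3 ended without DMSO array 3 (0.56) or without carbamazepine array 1 (0.57) or 2 (0.53). For cholesterol synthesis and SREBP2 targets, MVD, STARD4 and LPIN1 were the 3 of 21 that rose and 18 were not called (adjusted p = 1.4e-08, and adjusted p = 0.055 with an estimated correlation). Of 28 NRF2 targets, GCLM, GCLC, SRXN1, SLC7A11 and OSGIN1 rose and 23 were not called (adjusted p = 3.4e-05, and adjusted p = 0.18 with an estimated correlation). Counts adjusted over the list alone did not differ for these 5 lists. With the mean of each gene's probe sets carbamazepine changed 286 genes. CYP1A1, at 0.24 ± 0.35 and not called, stood at -1.75 with the BSA 6 h arrays in place of the 14 h arrays.

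Ketoconazole raised 22 of 23 immediate early genes (4 arrays against 4). FOS (Entrez 2353), a subunit of the AP-1 transcription factor, rose by 7.16 ± 0.33, C11orf96 by 7.01 ± 0.23, the gluconeogenic enzyme gene PCK1 by 5.55 ± 0.30 and ATF3 by 5.40 ± 0.14. The neutrophil chemokine gene CXCL8 (Entrez 3576) rose by 5.22 ± 0.15, from a DMSO mean of 5.57 ± 0.18 (SD) to 10.79 ± 0.13 (SD), and CXCL2 rose by 5.32 ± 0.24. The zinc exporter genes SLC30A2 and SLC30A1 rose by 6.22 ± 0.44 and 4.13 ± 0.20. Among the largest falls were DLG1, a scaffold protein gene, at -3.11 ± 0.14, FAM111B at -3.05 ± 0.21 and ZC3HAV1, an antiviral zinc finger protein gene, at -3.02 ± 0.10.

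With ketoconazole 22 of 23 immediate early genes rose and 1 was not called (median 3.09, adjusted p = 2.7e-34, and adjusted p = 8.2e-08 with an estimated correlation). Of 45 NF-kB targets, 26 rose, 3 fell (CD83, MAP3K8 and CX3CL1) and 16 were not called (median 0.66, adjusted p = 4.9e-09, and adjusted p = 0.0045 with an estimated correlation). These included TNFAIP3 (Entrez 7128), an inhibitor of NF-kB signalling, at 1.81 ± 0.20, and the inhibitor gene NFKBIA (Entrez 4792) at 1.64 ± 0.12. Of 29 ATF4 and CHOP targets, 15 rose and 14 were not called (median 0.72, adjusted p = 4.4e-17, and adjusted p = 4.1e-05 with an estimated correlation), with DDIT3 up by 5.35 ± 0.13. The zinc-binding metallothionein list had 5 risers of 10 (MT1F, MT1G, MT1M, MT1X and SLC30A1) and 5 not called (adjusted p = 1.6e-06, and adjusted p = 0.0075 with an estimated correlation), with MT1M up by 4.32 ± 0.53. Of 26 regulators of TNF receptor death signalling and apoptosis, 9 rose, 3 fell (FADD, BID and TNFSF10) and 14 were not called (adjusted p = 0.0023, and adjusted p = 0.0075 with an estimated correlation). The pro-apoptotic genes BIK, HRK and PMAIP1 rose by 3.57 ± 0.34, 2.98 ± 0.26 and 2.51 ± 0.15.

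Heat shock protein genes rose in 10 of 19 cases with ketoconazole, HSPE1 fell and 8 were not called (median 0.82, adjusted p = 0.004, and adjusted p = 0.39 with an estimated correlation), with HSPA6 up by 3.82 ± 0.55. In the G1/S and DNA replication list 22 of 29 fell and 7 were not called (median -0.89, adjusted p = 3.4e-18, and adjusted p = 0.0048 with an estimated correlation), with FEN1 at -2.32 ± 0.10 and PCNA at -1.80 ± 0.07. In the G2/M and mitosis list 17 of 31 fell and 14 were not called (median -0.62, adjusted p = 1.5e-08, and adjusted p = 0.28 with an estimated correlation). Respiratory chain genes lay lower as a group (median -0.41, adjusted p = 5.3e-09, and adjusted p = 0.0045 with an estimated correlation), although NDUFB8, CYC1 and COX7B were the 3 of 26 that fell and 23 were not called. Of 16 genes of PXR and CAR related drug metabolism, CYP3A7, ALAS1 and SULT2A1 rose, GSTA1 fell and 12 were not called (adjusted p = 0.15). The ER chaperone list had 3 risers, 3 fallers and 22 not called of 28 (adjusted p = 0.85). Its risers were DNAJB9, HERPUD1 and SEC24D and its fallers SDF2L1, CRELD2 and WFS1. Counts adjusted over the list alone were identical for the 11 lists named with ketoconazole. The 3 prime minus 5 prime difference of the ACTB control probe sets, a sign of RNA integrity, was -0.83 with ketoconazole relative to DMSO (exact 2-sided permutation p = 0.0286, adjusted p = 0.143). That p is the lowest that the 70 splits allow. The arrays did not overlap, at 0.74 to 1.19 with ketoconazole and 1.53 to 1.95 in DMSO. Between the ketoconazole and DMSO arrays with TNF for 6 h, CYP1A1 (-0.51 ± 0.35 and not called without TNF) stood at 3.24, CYP3A7 (0.62 ± 0.26) at -0.35, and TNFAIP3 and NFKBIA, no longer called, at 0.39 and 0.44. The CYP1A1 difference without TNF came mostly from ketoconazole array 4, at 6.75 against 9.20, 8.34 and 9.23 in arrays 1, 2 and 3. The call of CYP3A7 ended without DMSO array 2, 3 or 4 (0.46, 0.64 and 0.62) or ketoconazole array 1, 2 or 4 (0.67, 0.48 and 0.54), that of COX7B without DMSO array 1 (-0.56) or ketoconazole array 4 (-0.57), and that of GSTA1 (-1.60 ± 0.65) without 5 of the 8 arrays, at between -1.26 and -1.58.

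Methotrexate raised immediate early genes and p53 targets (3 arrays against 4). EGR1 rose by 3.54 ± 0.19, DEPP1, a target of FOXO factors, by 3.51 ± 0.42, the cytokine gene IL11 by 2.85 ± 0.26 and the fetal liver cytochrome gene CYP3A7 by 2.68 ± 0.28. CDKN1A (Entrez 1026), the p53 target that stops the cell cycle, rose by 1.44 ± 0.13, TP53I3 by 1.41 ± 0.16 and MDM2, which codes for the ubiquitin ligase of p53, by 0.90 ± 0.13. CYP1A1 changed by -2.20 ± 0.38, HMMR, a spindle protein gene, by -1.93 ± 0.12, and MAT2A, which codes for the enzyme that makes S-adenosylmethionine, by -1.81 ± 0.19. SLC19A1, the folate carrier that also takes up methotrexate, changed by -1.19 ± 0.11. The methotrexate group joined 2 arrays labelled 14 h, whose titles also name 6 h, with 1 labelled BSA 6 h. The DMSO arrays had no BSA. CYP1A1 averaged 6.69 in this group, 8.72 with methotrexate and BSA for 1 h, and 8.89 in DMSO. With BSA for 6 h against no addition CYP1A1 was lower after diclofenac and carbamazepine (not called after ketoconazole), and G2/M genes were lower after ketoconazole. Carrier and time cannot be told apart from the drug for such changes.

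With methotrexate 17 of 23 immediate early genes rose and 6 were not called (median 1.43, adjusted p = 1.7e-24, and adjusted p = 6.4e-06 with an estimated correlation). Of 26 p53 targets, 14 rose and 12 were not called (median 0.68, adjusted p = 2.5e-16, and adjusted p = 0.00032 with an estimated correlation). Of 31 G2/M and mitosis genes, 15 fell and 16 were not called (median -0.58, adjusted p = 1.5e-18, and adjusted p = 0.055 with an estimated correlation), with CDC20 at -1.53 ± 0.12 and KIF20A at -1.52 ± 0.15. The G1/S and DNA replication list had CCNE2 and CLSPN as risers and 27 of 29 not called (adjusted p = 0.95). Ribosome biogenesis genes fell in 9 of 29 cases and 20 were not called (median -0.38, adjusted p = 4.7e-18, and adjusted p = 0.012 with an estimated correlation), with RRS1 at -0.89 ± 0.08. In the folate and nucleotide synthesis list MTHFD1L, DHODH and SLC19A1 fell, IMPDH2 rose and 23 of 27 were not called (adjusted p = 0.37). The glycolysis and hypoxia list had 5 risers (SLC2A1, HK1, ENO2, NDRG1 and ANKRD37) and 19 not called of 24 (adjusted p = 0.00026, and adjusted p = 0.079 with an estimated correlation). Bile acid genes BAAT, SLC51B, NR0B2 and ABCC2 rose, AKR1D1 fell and 12 of 17 were not called (adjusted p = 0.1). Their median was -0.01, their mean 0.26 and the test pointed up. These 8 lists had equal counts when adjusted over the list alone. Between the arrays with TNF for 6 h, the change with methotrexate was -0.18 for CLSPN and 1.05 for CYP1A1, each of the opposite sign to that without TNF, and MTHFD1L stood at 0.02 with the mean of its probe sets. The call of CLSPN ended without DMSO array 1 (0.58) or 3 (0.55) or methotrexate array 2 (0.27).

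With nefazodone and BSA for 6 h, against DMSO without BSA, genes of DNA replication fell (3 arrays against 4). Targets of ATF4 and CHOP and immediate early genes rose. FAM111B changed by -3.75 ± 0.23, E2F8, an E2F-family repressor of the cell cycle, by -2.88 ± 0.23, the thymidine kinase gene TK1 by -2.58 ± 0.18 and GINS1 by -2.13 ± 0.12. RGCC rose by 4.03 ± 0.40, EGR1 by 3.97 ± 0.19, CXCL8 by 3.85 ± 0.17, ATF3 by 3.52 ± 0.15 and DDIT3 by 3.24 ± 0.14. The haptoglobin-related gene HPR changed by -2.77 ± 0.24.

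With nefazodone 27 of 29 G1/S and DNA replication genes fell and 2 were not called (median -1.27, adjusted p = 3.8e-38, and adjusted p = 3.6e-05 with an estimated correlation), and 24 of 31 G2/M and mitosis genes fell and 7 were not called (median -0.76, adjusted p = 9e-15, and adjusted p = 0.11 with an estimated correlation). ATF4 and CHOP targets rose in 22 of 29 cases and 7 were not called (median 1.08, adjusted p = 8e-27, and adjusted p = 3.6e-07 with an estimated correlation), and immediate early genes in 19 of 23 with 4 not called (median 1.44, adjusted p = 4e-22, and adjusted p = 1.3e-05 with an estimated correlation). Cholesterol synthesis and SREBP2 targets included 7 risers, 3 fallers (PMVK, EBP and TM7SF2) and 11 not called of 21 (adjusted p = 0.0002, and adjusted p = 0.2 with an estimated correlation). The transcription factor gene SREBF2 rose by 1.22 ± 0.11 and DHCR7, the last enzyme of cholesterol synthesis, by 1.07 ± 0.09. Autophagy and lysosome genes rose in 10 of 27 cases and 17 were not called (adjusted p = 7.5e-06, and adjusted p = 0.064 with an estimated correlation), with MAP1LC3B up by 1.59 ± 0.10 and NPC1 by 1.25 ± 0.09. Of 24 interferon stimulated genes, 8 fell, IRF9 rose and 15 were not called (median -0.36, adjusted p = 0.013, and adjusted p = 0.31 with an estimated correlation). Acute phase protein genes SAA4, HP, HPX and C4BPB fell, HAMP rose and 13 of 18 were not called (adjusted p = 0.14). Among hepatocyte products and transcription factors TAT and PCK1 rose, APOC3, APOM, F7, CEBPA and FOXA1 fell and 23 of 30 were not called (adjusted p = 0.14), and APOC3 lost its call without nefazodone array 3 (-0.63). Of 17 PPARA targets, PLIN2 and VNN1 rose, CPT2, SLC25A20, ACAA2 and EHHADH fell and 11 were not called (adjusted p = 0.094). Adjusted over the list alone the counts of these 10 lists were no different. Of 26 ribosomal protein genes 0 were called in limma with each of the 5 drugs, also when adjusted over the list alone, while between 2 and 6 had an unadjusted p below the threshold (list adjusted p = 0.41 with nefazodone). The nefazodone arrays had 6 h of BSA and the DMSO arrays none. With BSA for 6 h against no addition, G2/M and G1/S genes, E2F8 among them, were lower after ketoconazole. Carrier and time cannot be told apart from nefazodone for such changes. The ACTB difference of the nefazodone arrays was -0.34 (exact 2-sided permutation p = 0.0857, adjusted p = 0.214). SOD2, at -0.17 ± 0.12 and not called, stood at 0.89 between the arrays with TNF for 6 h.

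A further count asked which changes the 5 drugs had in common. In all, 64 genes rose and 18 fell with every drug. The number was at most 0 in 20 simulated sets of unchanged groups sharing the same DMSO arrays, and 0.0039 would be expected of independent lists. Neither tells how many genes 5 drugs with real effects would share against a common control. ATF3 rose with each drug, by 2.40, 1.44, 5.40, 1.70 and 3.52 in the order diclofenac, carbamazepine, ketoconazole, methotrexate and nefazodone, and EGR1 by 3.27, 1.12, 5.08, 3.54 and 3.97. SLC51B, a bile acid exporter subunit, rose by between 0.87 and 1.65. Of the ATF4 and CHOP targets ATF3, SESN2, GDF15, NUPR1 and JDP2 rose with all 5 drugs, of the immediate early genes EGR1 and ZFP36, and of the apoptosis regulators CASP10 and PMAIP1. Genes chosen after their values were seen included IGFBP1, which binds insulin-like growth factors, with rises from 1.38 to 2.13, CCNG2 from 1.38 to 3.00 and the lysosomal peptidase gene DPP7, with changes from -0.87 to -3.01. With the DMSO arrays split into 2 pairs, of which 1 served 3 of the drugs and the other the remaining 2, between 67 and 87 genes were common to all 5. Drugs still shared control arrays, so part of the count may come from them. The mean of probe sets gave 46, and the arrays with TNF for 6 h on both sides gave 150, of which 112 rose and 38 fell.

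The control comparisons asked how drug-treated cells with BSA for 6 h differed from those at 14 h without addition (4 arrays against 4 for each drug). CYP1A1 changed by -2.13 ± 0.35 with diclofenac and -1.99 ± 0.35 with carbamazepine, and by -0.29 ± 0.35, which was not called, with ketoconazole. With ketoconazole ATP6V0D2, a proton pump subunit, rose by 4.15 ± 0.22 and the matrix protease gene MMP3 by 3.44 ± 0.27, while E2F8 changed by -2.04 ± 0.21 and KIF20A by -1.36 ± 0.14. In all, 76 genes rose and 61 fell with diclofenac, 10 and 23 with carbamazepine, and 624 and 996 with ketoconazole. In the ketoconazole arrays 22 of 31 G2/M and mitosis genes fell and 9 were not called (median -0.79, adjusted p = 3.4e-26, and adjusted p = 0.056 with an estimated correlation), and 11 of 29 G1/S genes fell and 18 were not called (adjusted p = 5.9e-11, and adjusted p = 0.095 with an estimated correlation), with the same counts adjusted over the list alone. With diclofenac the zinc exporter gene SLC30A1 changed by -0.95 ± 0.20. Over 15399 genes the root mean square distance of the 14 h arrays was 0.133 to the BSA 1 h arrays and 0.187 to the BSA 6 h arrays with diclofenac, 0.108 and 0.155 with carbamazepine, and 0.132 and 0.372 with ketoconazole. With the mean of probe sets the 3 comparisons called 67, 17 and 1072 genes, and with the replicate number as a block carbamazepine gave 59. Without BSA 6 h array 2 carbamazepine gave 20.

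TNF for 1 h in DMSO-treated cells raised 23 of 45 NF-kB targets (4 arrays against the 4 DMSO arrays at 14 h). CXCL2 rose by 4.92 ± 0.24, CXCL8 by 4.52 ± 0.15, TNFAIP3 by 4.24 ± 0.20 and CXCL1 by 4.07 ± 0.25. The transcription factor gene IRF1 rose by 3.18 ± 0.18, NFKBIA by 2.93 ± 0.12, the adhesion molecule gene ICAM1 by 2.35 ± 0.17 and JUN by 2.28 ± 0.13. In all 73 genes rose and 9 fell. The fallers were 5 zinc finger genes (ZNF449, ZNF684, ZNF92, ZNF248 and ZNF780A), RSRP1, HEY1, ARRDC3 and SPRY1, with changes between -0.61 and -0.80. Apart from those of ARRDC3 and RSRP1, their calls ended when at least 1 of the 8 arrays was left out, at changes between -0.46 and -0.75. NF-kB targets rose in 23 of 45 cases (25 adjusted over the list alone) and 22 were not called, with a median of 0.64, adjusted p = 5.1e-183, and adjusted p = 5.6e-25 with an estimated correlation. Feedback genes of TNF and NF-kB signalling rose in 6 of 17 cases and 11 were not called (adjusted p = 3.9e-51, and adjusted p = 8.7e-17 with an estimated correlation), and 6 of 23 immediate early genes rose with 17 not called (adjusted p = 5.1e-31, and adjusted p = 1.4e-07 with an estimated correlation), both with 6 adjusted over the list alone. The control cells had 14 h in all and no BSA, so time and carrier differed as well.

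TNF for 6 h in DMSO-treated cells raised 25 of 45 NF-kB targets (4 arrays against the 4 DMSO arrays at 14 h, which had no BSA, so carrier differed as well). CXCL8 rose by 3.93 ± 0.15, TNFAIP3 by 3.04 ± 0.20, ICAM1 by 2.68 ± 0.17, CXCL2 by 2.52 ± 0.24 and the transcription factor gene GATA6 by 2.12 ± 0.19. The superoxide dismutase gene SOD2 rose by 1.22 ± 0.11. CYP1A1 changed by -4.17 ± 0.35, from a mean of 8.89 ± 0.29 (SD) to 4.72 ± 0.57 (SD). BSA for 6 h against no addition changed it by -2.13 with diclofenac and -1.99 with carbamazepine, while it was not called with ketoconazole. The carrier, or another difference of the 14 h arrays, could account for part of the change in DMSO. The vitamin D hydroxylase gene CYP24A1 changed by -1.78 ± 0.26, and HAMP, which codes for the iron hormone hepcidin, by -1.21 ± 0.18. In all 108 genes rose and 58 fell. NF-kB targets rose in 25 of 45 cases, also when adjusted over the list alone, and 20 were not called (median 0.82, adjusted p = 1.8e-104, and adjusted p = 2.1e-18 with an estimated correlation). Interferon stimulated genes IFIT1, IFIT3, ISG20, RIGI and IFIH1 rose (6 adjusted over the list alone) and 19 of 24 were not called (adjusted p = 8e-08, and adjusted p = 0.028 with an estimated correlation), with IFIT3, an antiviral protein gene, at 1.35 ± 0.32. The call of IFIT1 ended without DMSO 14 h array 3 (0.79) or TNF 6 h array 2 (0.78) or 4 (0.82). The NRF2 targets GCLM and SRXN1 fell and 26 of 28 were not called (adjusted p = 7.4e-06, and adjusted p = 0.19 with an estimated correlation), with 2 adjusted over the list alone. GCLM lost its call without DMSO 14 h array 1 (-0.55) or TNF 6 h array 3 (-0.57) or 4 (-0.52).

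**Figure D2:**
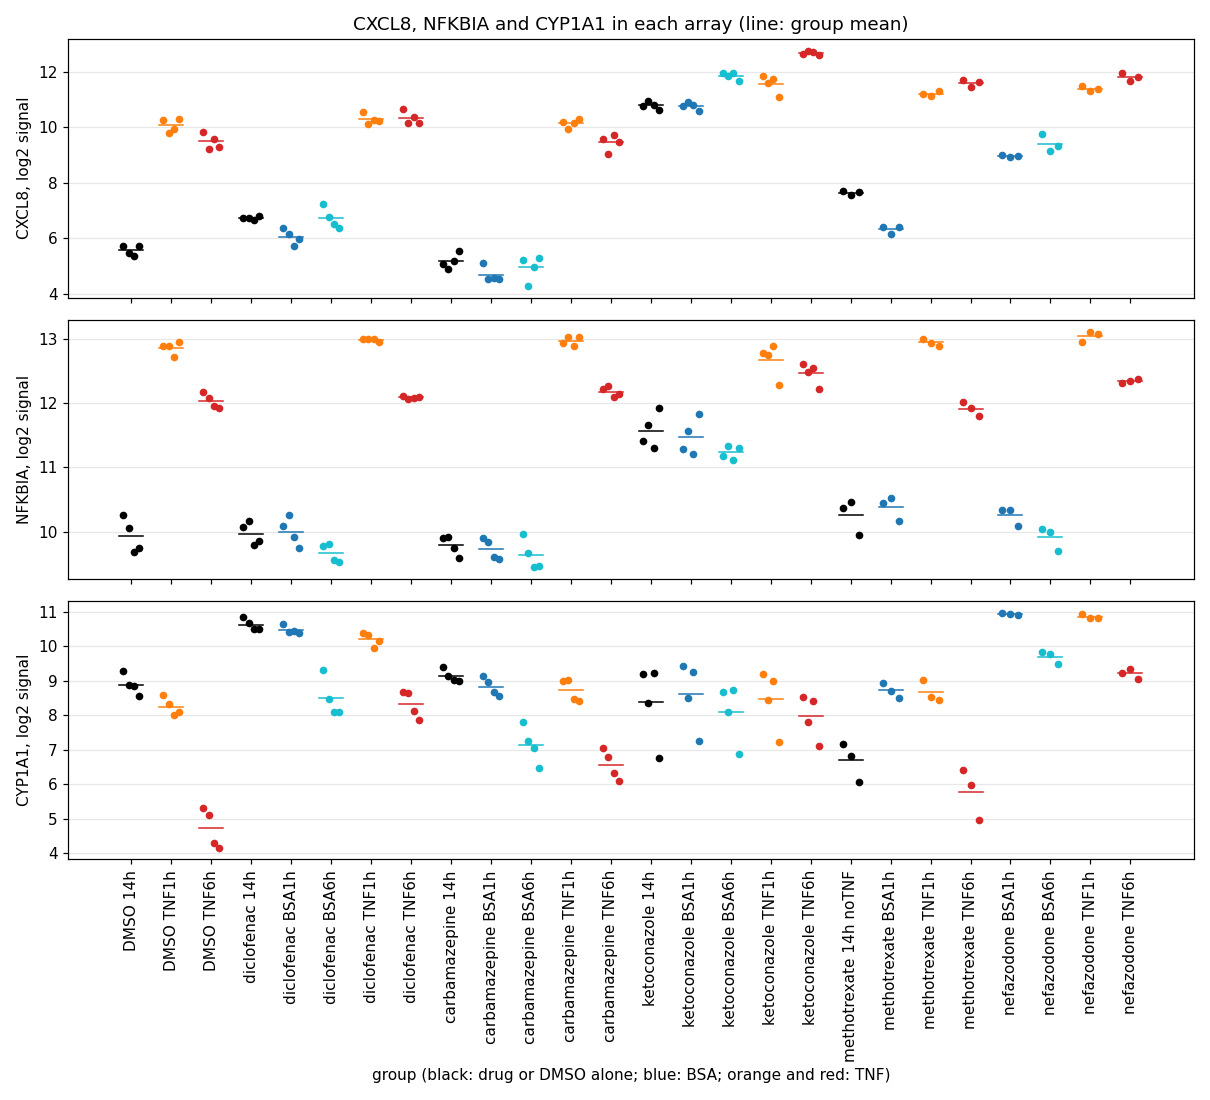
Points give the log2 signal of CXCL8, NFKBIA and CYP1A1 in each array (vertical axes) by group (horizontal axis), and lines give group means. CXCL8 averaged 5.57 in DMSO at 14 h and 10.79 with ketoconazole at 14 h, and CYP1A1 averaged 4.72 in DMSO with TNF for 6 h.

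TNF for 1 h after a drug was compared with BSA for 1 h after the same drug, with 4 arrays a group for diclofenac, carbamazepine and ketoconazole and 3 for methotrexate and nefazodone. TNFAIP3 rose by 4.96 ± 0.20 with diclofenac, 4.89 ± 0.20 with carbamazepine, 4.54 ± 0.23 with methotrexate and 4.47 ± 0.23 with nefazodone, and by 2.29 ± 0.20 with ketoconazole. CXCL2 rose by 5.96 ± 0.24, 5.35 ± 0.24, 7.51 ± 0.28, 4.90 ± 0.28 and 1.80 ± 0.24 in the same order, and NFKBIA by 3.00 ± 0.12, 3.25 ± 0.12, 2.57 ± 0.13, 2.80 ± 0.13 and 1.2 ± 0.12. CXCL8 rose by 4.23 ± 0.15 with diclofenac, 5.46 ± 0.15 with carbamazepine, 4.87 ± 0.18 with methotrexate, 2.43 ± 0.18 with nefazodone and 0.79 ± 0.15 with ketoconazole. With ketoconazole ICAM1 differed by 0.57 ± 0.17 and SOD2 by 0.32 ± 0.11, neither called. The call of CXCL8 with ketoconazole ended without TNF 1 h array 1 (0.71) or 3 (0.74), and with the groups of that comparison alone in the fit neither CXCL8 nor TNFAIP3 was called (adjusted p = 0.1 and 0.053).

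In these comparisons 63 genes rose and AXIN2 fell with diclofenac, 81 rose and ZNF92 fell with carbamazepine, and 70 rose and 4 fell (ARRDC3, FOXA2, ZNF57 and MRAP, the last named after its values were seen) with methotrexate. With nefazodone 51 rose and ARRDC3 and AXIN2 fell, and with ketoconazole 14 rose and 0 fell (limma, 835 genes at an unadjusted p below the threshold). Of 45 NF-kB targets the risers numbered 25 with diclofenac (26 adjusted over the list alone), 25 with carbamazepine (25), 24 with methotrexate (26), 22 with nefazodone (27) and 13 with ketoconazole (14). Those lists passed the test with either correlation, the adjusted p with ketoconazole being 2.2e-51, and 1.3e-11 with an estimated correlation. Without ketoconazole TNF 1 h array 4 the ketoconazole count was 22 genes, and with the groups of that comparison alone in the fit it was 3.

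TNF for 6 h after a drug was compared with BSA for 6 h after the same drug, with the same numbers of arrays. For methotrexate the control was the group without TNF, in which 2 arrays were labelled 14 h and 1 BSA 6 h. ICAM1 rose by 3.10 ± 0.17 with diclofenac, 3.27 ± 0.17 with carbamazepine, 2.33 ± 0.17 with ketoconazole, 3.31 ± 0.20 with methotrexate and 3.37 ± 0.20 with nefazodone. SOD2 rose by 1.88 ± 0.11, 1.74 ± 0.11, 1.62 ± 0.11, 1.65 ± 0.13 and 2.28 ± 0.13 in that order, and CXCL8 by 3.61 ± 0.15, 4.51 ± 0.15, 0.82 ± 0.15, 3.96 ± 0.18 and 2.40 ± 0.18. The lymphotoxin gene LTB rose by 4.42 ± 0.25 with methotrexate, the urokinase gene PLAU by 3.48 ± 0.29 with nefazodone, and the cytokine gene IL23A by 2.58 ± 0.22 with ketoconazole. MIXL1, a developmental homeobox gene, changed by -1.33 ± 0.20 with diclofenac, -1.68 ± 0.20 with carbamazepine and -2.55 ± 0.23 with methotrexate. CYP1A1 was not called with any drug, with differences of -0.17 ± 0.35, -0.58 ± 0.35, -0.13 ± 0.35, -0.91 ± 0.41 and -0.49 ± 0.41.

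With TNF for 6 h, 94 genes rose and 15 fell with diclofenac, 170 and 16 with carbamazepine, 121 and 32 with methotrexate, and 143 and 14 with nefazodone. With ketoconazole 79 rose and 5 fell (DHRS11, DYNC2I2, SPA17, and LINC00261 and THBD, both named after their values were seen). DHRS11 lost its call without BSA 6 h array 3 (-0.59), and DYNC2I2 without BSA 6 h array 3 (-0.56) or 4 (-0.51) or TNF 6 h array 1 (-0.55) or 2 (-0.46). NF-kB targets rose in 24 of 45 cases with diclofenac (25 adjusted over the list alone), 28 with carbamazepine (28), 28 with ketoconazole (29), 29 with methotrexate (29) and 30 with nefazodone (32), and passed the test with either correlation. Of 24 interferon stimulated genes 6 rose with diclofenac (9 adjusted over the list alone), 8 with carbamazepine (8), 4 with methotrexate (5, the 4 being ISG20, GBP2, RIGI and IFIH1) and 7 with nefazodone (8), also with either correlation. With ketoconazole 0 of the 24 did in limma, where 6 had an unadjusted p below the threshold, and the list adjusted p was 0.039, and adjusted p = 0.47 with an estimated correlation. With the arrays at 14 h without BSA as control, TNF for 6 h changed 298 genes with diclofenac (175 up and 123 down), 243 with carbamazepine (180 and 63) and 2224 with ketoconazole (816 and 1408). With ketoconazole 38 genes were called with these groups alone in the fit, and 128 without TNF 6 h array 4. The mean of probe sets gave 123 with carbamazepine.

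The last planned comparisons asked whether a drug altered the response to TNF at 6 h, as the difference between the change with the drug and that in DMSO. CYP1A1 had a positive difference in each drug arm, of 3.99 ± 0.50 with diclofenac, 3.59 ± 0.50 with carbamazepine, 4.04 ± 0.50 with ketoconazole, 3.25 ± 0.54 with methotrexate and 3.67 ± 0.54 with nefazodone. With the 14 h arrays as control it was not called with diclofenac (1.86, adjusted p = 0.054) or carbamazepine (1.60, adjusted p = 0.52). For CXCL8 the response was smaller with ketoconazole, by -3.10 ± 0.22, and with nefazodone, by -1.52 ± 0.24, the latter not called with the mean of its probe sets (-1.12). With ketoconazole the epithelial transcription factor gene ELF3 differed by -1.62 ± 0.20 and GATA6 by -1.54 ± 0.27. Larger responses were those of IL23A with ketoconazole (2.40 ± 0.31), LTB with methotrexate (2.68 ± 0.34) and PLAU with nefazodone (1.88 ± 0.39).

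By this test 13 genes were higher and 5 lower with diclofenac (CCNG2, CDK19, ELF3, OGT, and CXCL5, named after its values were seen), 8 and 2 with carbamazepine (CDK19 and MAP2K6), 28 and 35 with ketoconazole, 9 and 3 with methotrexate (CCL20, ELF3 and MAP2K6), and 21 and 7 with nefazodone. Of 45 NF-kB targets with ketoconazole, NFKBIA, CXCL8, CXCL2, CCL20 and SDC4 were lower, BCL2A1 was higher and 39 were not called (5 higher and 7 lower adjusted over the list alone, list adjusted p = 0.15). The nefazodone list had SOD2, TNFRSF9 and PLAU higher, CXCL8 and CCL20 lower and 40 not called (13 and 3 adjusted over the list alone, median 0.34, adjusted p = 6e-12, and adjusted p = 0.0022 with an estimated correlation). G2/M and mitosis genes had medians of -0.28 with diclofenac, -0.36 with carbamazepine, -0.39 with ketoconazole, -0.29 with methotrexate and -0.33 with nefazodone, and the adjusted p with an estimated correlation were 0.2, 0.088, 0.28, 0.41 and 0.16. With ketoconazole KIF20A was lower (2 adjusted over the list alone, and no call without BSA 6 h array 4, at -0.70), and 0 of the 31 were called with the other drugs in limma, where 8 to 18 had an unadjusted p below the threshold. The DMSO control had no BSA and the drug controls did, although this is unsettled for the 2 methotrexate arrays labelled 14 h, as the title of 1 names BSA. With the 14 h arrays as control the counts were 70 with diclofenac (30 higher and 40 lower), 6 with carbamazepine (2 and 4) and 2019 with ketoconazole (805 and 1214), and the difference of OGT with diclofenac was 0.05. With the replicate number as a block, which pairs the arrays of the carbamazepine and methotrexate comparisons, the counts were 33 and 44, and for diclofenac, ketoconazole and nefazodone they were 35, 117 and 50. The diclofenac count was between 6 and 11 without 13 of the 16 arrays, the carbamazepine count was 6 without BSA 6 h array 2, and the methotrexate count was 7 without DMSO 14 h array 2 and 19 without methotrexate TNF 6 h array 2. The nefazodone count was 18 without TNF 6 h array 3.

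**Figure D3:**
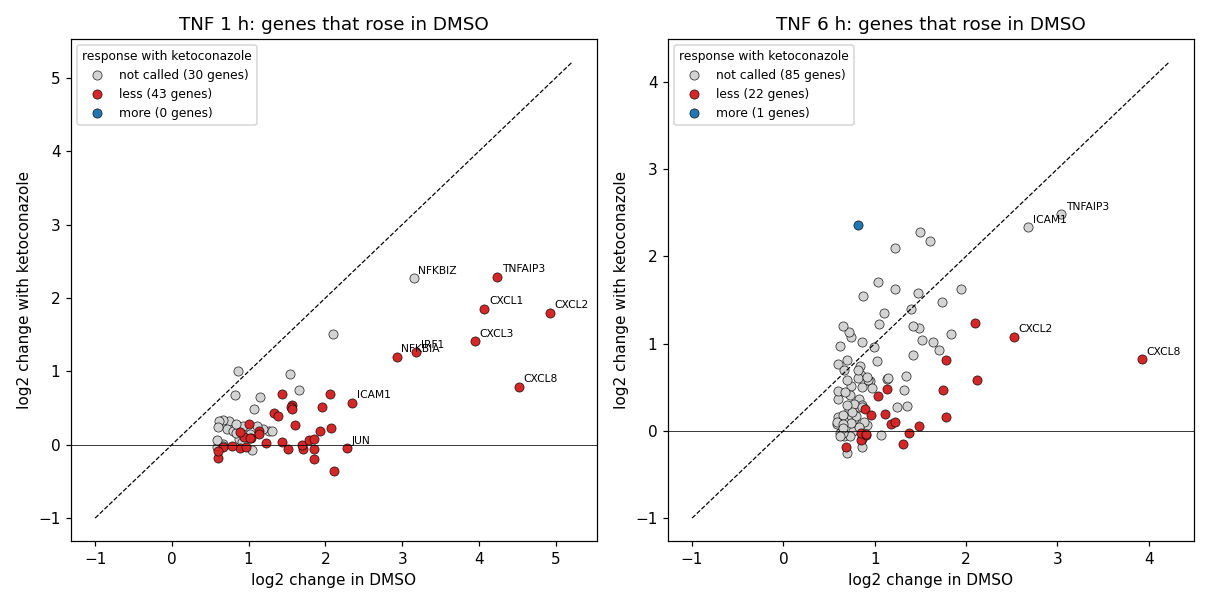
Points give the log2 change with TNF after ketoconazole (vertical axes) against that in DMSO (horizontal axes) for the 73 genes that rose in DMSO at 1 h and the 108 that rose at 6 h, with the dashed line at equal change and colours for the test of the difference. At 1 h 43 genes rose less with ketoconazole and 0 more, and at 6 h 22 rose less and 1 more.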

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

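The splits of the arrays and the correlation between starting level and response were chosen before their results were seen, and the other tests of explanations here, with the splits of the responses that keep pairs, after.

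Single arrays stood apart from the other 3 of their group, with a gap above the critical share of the range in Dixon's test, in 20 of 342 sets of 4 values (19 genes in 18 groups), where chance gives about 1 in 20. Among the carbamazepine arrays these were CXCL8 in BSA 1 h array 1 (5.12) and MDM2 in array 3 (8.76), TNFAIP3 (6.85) and HMOX1 (8.24) in BSA 6 h array 1, HMGCS1 in BSA 6 h array 4 (10.04), ATF3 in TNF 1 h array 3 (8.19) and HMGCS1 in TNF 1 h array 4 (10.51). Among the diclofenac arrays they were TNFAIP3 (7.95) and MDM2 (9.38) in 14 h arrays 2 and 4, TRIB3 (10.77) and CYP1A1 (10.63) in BSA 1 h arrays 3 and 1, and HSPA5 in TNF 1 h array 3 (12.68). In DMSO they were TNFAIP3 in 14 h array 1 (7.25) and HSPA5 in TNF 6 h array 3 (12.43). Among the ketoconazole arrays they were TRIB3 in 14 h array 4 (10.95), HMOX1 in 14 h array 2 (10.19), ALB in BSA 1 h array 1 (13.21), ICAM1 (8.15) and DDIT3 (11.70) in TNF 1 h array 4, and ATF3 in TNF 6 h array 4 (11.04).

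The response to TNF for 6 h differed from that in DMSO by a test of the difference for 18 genes with diclofenac, 10 with carbamazepine, 63 with ketoconazole, 12 with methotrexate and 28 with nefazodone. At 1 h the difference held for 3 genes with diclofenac (DDIT4 higher, JUN and MAFF lower), 1 with carbamazepine (DDIT4), 47 with ketoconazole, 7 with methotrexate and 12 with nefazodone. The DMSO control at 1 h had 14 h in all and no BSA, unlike the drug controls. Of 100 splits of the arrays within the same treatment, the number with as many genes at 6 h, the real split included, was 1 with diclofenac (highest other 1 gene), 2 with carbamazepine (highest other 168), 3 with ketoconazole (highest other 319), 1 with methotrexate (highest other 6) and 1 with nefazodone (highest other 3). At 1 h it was 1 with diclofenac (highest other 1), 2 with carbamazepine (highest other 1), 1 with ketoconazole (highest other 44), 1 with methotrexate (highest other 1) and 1 with nefazodone (highest other 4). The share of these splits was under 0.05 in each case. Where drug and DMSO arrays changed places only with arrays of the same number, the number with as many genes at 6 h was 1 of 100 with diclofenac (highest other 4), 1 of 100 with carbamazepine (4), 5 of 100 with ketoconazole (126), 1 of 64 with methotrexate (3) and 1 of 64 with nefazodone (5). At 1 h it was 1 of 100 (highest other 0), 3 of 100 (2), 1 of 100 (31), 1 of 64 (3) and 1 of 64 (4) in the same order. Both kinds of split argued against chance at 6 h with each drug but ketoconazole, and at 1 h for methotrexate and nefazodone. At 1 h with ketoconazole both shares were under 0.05, but another split called 44 genes against the real 47. The comparisons at 1 h were also chosen after the data had been seen, so chance was not held to be excluded there. With ketoconazole at 6 h the share of the second kind was not under 0.05, and chance was not held to be excluded. There the numbers paired the arrays within each arm, with correlations from 0.253 to 0.633 with ketoconazole and from 0.178 to 0.22 in DMSO. Between ketoconazole and DMSO not every such pair exceeded 0.1. The counts of 3 and 1 at 1 h with diclofenac and carbamazepine were not held to exclude chance, since leaving out single arrays gave as few as 1 and 0, and other splits with carbamazepine called up to 2 genes. The splits with 168 and 319 genes call several times the real count, which points to a structure among the arrays.

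For the drugs against DMSO, 1 of 35 splits gave as many genes as the real split in each case, which argues against chance. For ketoconazole and nefazodone not every pair of the same number exceeded 0.1. Their median correlations of 0.116 and 0.168 leave a pairing open, so chance was not held to be excluded. The real and the highest other counts were 1421 and 221 with diclofenac, 448 and 33 with carbamazepine, 3671 and 1133 with ketoconazole, 1373 and 773 with methotrexate, and 3153 and 2041 with nefazodone. With methotrexate and nefazodone that highest other split kept all drug arrays together with 1 DMSO array, close to the real split. The median of the other splits was 0 with these 2 drugs. The same held, with 1 of 35, for TNF in DMSO at 1 h (82 and 25) and 6 h (166 and 22), TNF with diclofenac at 1 h (64 and 17) and 6 h (109 and 20), and TNF with carbamazepine at 1 h (82 and 30) and 6 h (186 and 44). It also held for BSA 6 h with diclofenac (137 and 6), carbamazepine (33 and 5) and ketoconazole (1620 and 1000). In all of these but the comparisons of ketoconazole and nefazodone with DMSO every such pair exceeded 0.1. The 8 splits that part every pair, the real one included, were too few for a share under 0.05 in any of them. Among these 8 the highest others against DMSO were 179 with diclofenac, 13 with carbamazepine, 1130 with ketoconazole, 641 with methotrexate and 1927 with nefazodone. They were 17 and 11 for TNF in DMSO at 1 h and 6 h, 10 and 7 with diclofenac, 27 and 21 with carbamazepine, and 0, 0 and 359 for BSA 6 h with diclofenac, carbamazepine and ketoconazole. The higher counts given first came from splits that leave at least 1 pair together. With methotrexate and nefazodone the 10 splits of 3 against 3 arrays were too few for a share under 0.05. Their real and highest other counts were 74 and 1, and 53 and 0, at 1 h, and 153 and 4, and 157 and 1, at 6 h.

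With ketoconazole 11 of 35 splits gave as many genes as the 14 of TNF for 1 h (highest other 351), and 12 of 35 as many as the 84 of TNF for 6 h (highest other 338), so these splits did not exclude chance for the counts. Of the 14 risers at 1 h, 12 were among the 73 genes that rose with TNF in the DMSO arrays. At 6 h 41 of the 79 risers were among the 108 that rose in DMSO. This overlap argues against chance for the genes in it. The highest splits set arrays 1 and 3 of both groups against arrays 2 and 4, a structure of the samples by replicate number. Among splits that part as many pairs as the real split, the highest others were 11 genes at 1 h and 33 at 6 h, and with the replicate number as a block the counts were 15 and 98.

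The drug arrays labelled 14 h without addition lay near the BSA 1 h arrays and away from the BSA 6 h arrays of the same drug, with at most 5 genes called against the former in limma, and 137 with diclofenac, 33 with carbamazepine and 1620 with ketoconazole against the latter. Spread between arrays was argued against over all splits, since at most 1 of 35 per drug gave as many genes, although the 8 that part every pair are too few to decide it. On a scale with 0 at BSA 1 h and 1 at BSA 6 h, with separate BSA 1 h arrays for the direction and the zero, the highest position of the 3 drugs was 0.03. With the same BSA 1 h arrays for both, single arrays lay between 0.22 and 0.31 with diclofenac, 0.17 and 0.26 with carbamazepine, and -0.20 and 0.13 with ketoconazole. All lay nearer BSA 1 h than BSA 6 h, so sampling earlier than the label says may be a cause. An effect of 6 h with BSA stays open too, because the lower of the methotrexate arrays labelled 14 h lay at 0.70 over 41 genes, but titles of these arrays name 6 h and in 1 case BSA. These explanations cannot be told apart, and no biological explanation was tested.

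CYP1A1 differed by less with TNF for 6 h in each drug arm than in DMSO, and the controls differed in BSA. With the 14 h arrays without BSA as control the difference was 1.86 ± 0.50 with diclofenac (adjusted p = 0.054) and 1.60 ± 0.50 with carbamazepine (adjusted p = 0.52). Both differences lay well beyond their SE from 0, which goes against the unequal controls as the whole cause. Neither was called over all genes, however, so this was not decided. The controls could be part of the cause there and cannot be told apart from an effect of the drug. With ketoconazole it was 3.75 ± 0.50 (adjusted p = 7e-09), which argues against the controls as the whole cause in that arm. An effect of ketoconazole on the response of CYP1A1 stays open, untested.

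Of the 108 genes that rose with TNF for 6 h in DMSO, 22 rose less under ketoconazole and BCL2A1 rose more, with a median difference of -0.55. A ceiling of the array scale as the whole cause was argued against, since 17 of the 22 lay over 3 log2 units below the highest value. A higher starting level under ketoconazole as the whole cause was argued against by 10 genes that started under 1.5-fold above DMSO. For a change of the DMSO arrays other than by TNF, 20 genes rose with TNF in at least 1 other drug arm. That shows a response to TNF, not whether the DMSO control enlarged the difference, and CDK19 and ELF3 were lower with other drugs too. Against the same DMSO arrays, whose response also chose the 108 genes, the medians were -0.22 with diclofenac, 0.12 with carbamazepine, -0.01 with methotrexate and 0.00 with nefazodone. These medians argue against the DMSO arrays as the whole cause of the median of -0.55. For the genes that started higher, the starting level may contribute, as Spearman correlations across genes of 0.01 and -0.01 between starting level and response decided nothing, and genes are not independent replicates. The second kind of split above did not exclude chance for the 6 h count with ketoconazole. Of the genes fixed before the data were examined, CXCL8 differed by -3.10 ± 0.22 and NFKBIA by -0.87 ± 0.16, which argues against chance for these. TNFAIP3 (-0.56) and ICAM1 (-0.35) were not called, nor was SOD2, which went the other way (0.40). CXCL8 started at 11.86 under ketoconazole and at 5.57 in DMSO, and NFKBIA at 11.24 and 9.94, so a higher starting level stays open for both. With ketoconazole and TNF they averaged 12.69 and 12.47, within 3 log2 units of the highest value, 13.81. The 17 genes above therefore do not speak to a ceiling for these genes. An effect of ketoconazole on TNF signalling stays open as a hypothesis.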

How the results depend on the processing

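The ketoconazole arrays numbered 4 left out, TNF for 6 h on both sides, the single methotrexate array labelled BSA 6 h and each setting for the response at 1 h were chosen after seeing the data. Of 1384 values of named genes, 941 were called. The number that lost the call was 0 with the filter on dim genes, 5 with the replicate block, 13 with quantile normalization, 23 without the trend, 37 with only the groups of the comparison in the fit, 162 with the mean of probe sets (1 reversed) and 168 over the arrays left out in turn (0 reversed). Of 675 list tests the first 6 of these settings, without the arrays left out, ended between 0 and 28 calls, added between 0 and 31 and reversed 0. Under quantile normalization the median shift of the gene values of an array was at most 0.0684.

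With the mean of probe sets the counts were 17 (carbamazepine), 67 (diclofenac) and 1072 (ketoconazole) for BSA 6 h, 10 for the 6 h response with diclofenac, 123 for TNF 6 h with carbamazepine, 286 for carbamazepine alone and 46 for all 5 drugs. With the replicate block they were 59 for BSA 6 h with carbamazepine, 35, 33, 117, 44 and 50 for the 6 h response with diclofenac, carbamazepine, ketoconazole, methotrexate and nefazodone, and 4 and 6 for the 1 h response with carbamazepine and diclofenac. With only the groups of the comparison in the fit they were 3 and 38 for TNF 1 h and 6 h with ketoconazole, and 17, 35 and 44 for the 6 h response with carbamazepine, ketoconazole and nefazodone. For the 1 h response with carbamazepine the count was 0. Fewer arrays set the spread in this setting, but counts did not all fall, as TNF 1 h gave 67 with diclofenac and 63 with nefazodone. The lowest mean correlation of an array with its own group was 0.9922 or less in each ketoconazole group and 0.9938 or more elsewhere. A spread shared by all groups may thus be too small for ketoconazole. Without the trend the counts were 7 and 1 for the 6 h and 1 h responses with diclofenac. With the 14 h arrays as control they were 6, 70 and 2019 for the 6 h response with carbamazepine, diclofenac and ketoconazole, and 298 and 2224 for TNF 6 h with diclofenac and ketoconazole. Without the ketoconazole arrays numbered 4 TNF 1 h gave 22, and TNF 6 h on both sides gave 150 for all 5 drugs.

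With TNF for 6 h on both sides the change against DMSO reversed for CYP1A1 with ketoconazole (3.24) and methotrexate (1.05), CYP3A7 with ketoconazole (-0.35), CLSPN (-0.18) and MT1X (0.06) with methotrexate, SLC30A1 with carbamazepine (-0.22), SLC39A10 with methotrexate (-0.09) and nefazodone (-0.02) and SOD2 with nefazodone (0.89). CYP1A1 reversed with carbamazepine (-1.75) and diclofenac (-0.39) for the BSA 6 h arrays in place of the 14 h arrays, MTHFD1L with methotrexate (0.02) for the mean of probe sets, and OGT in the 6 h response with diclofenac (0.05) for the 14 h arrays as control. The cause of these changes was not tested.

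With each array left out in turn the counts ranged from 20 (without BSA 6 h array 2) to 27 for BSA 6 h with carbamazepine, 11 to 22 (without TNF 1 h array 4) and 79 to 128 (without TNF 6 h array 4) for TNF 1 h and 6 h with ketoconazole. For the 6 h response they ranged from 6 (without BSA 6 h array 2) to 15 with carbamazepine, 6 to 23 with diclofenac, 7 (without DMSO 14 h array 2) to 19 (without TNF 6 h array 2) with methotrexate and 18 (without TNF 6 h array 3) to 29 with nefazodone. With diclofenac 13 of 16 arrays moved it, the exceptions being DMSO TNF 6 h array 1, BSA 6 h array 1 and TNF 6 h array 4. For the 1 h response they ranged from 0 (without DMSO 14 h array 2, DMSO TNF 1 h array 3 or 4, BSA 1 h array 4 or TNF 1 h array 3) to 2 (without BSA 1 h array 1) with carbamazepine, and 1 (without DMSO 14 h array 2 or 3, DMSO TNF 1 h array 3 or 4, BSA 1 h array 4 or TNF 1 h array 2 or 3) to 4 with diclofenac. They ranged from 4 (without BSA 1 h array 3 or TNF 1 h array 2 or 3) to 7 with methotrexate and 7 (without DMSO TNF 1 h array 4, BSA 1 h array 1 or TNF 1 h array 2) to 12 with nefazodone. The other counts stayed within 1.5-fold under each setting run. The filter on dim genes, set by the array median, removed 4375 of 19774 genes, and no background level was measured.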

Other observations

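The comparisons of the response to TNF for 1 h were chosen after the response at 6 h had been seen. Of the 73 genes that rose with TNF for 1 h in DMSO, 43 rose less under ketoconazole and 0 rose more by limma's test of the difference, with a median difference of -0.94, and 12 of the 73 were also called after ketoconazole. CXCL8 differed by -3.72 ± 0.22, CXCL2 by -3.12 ± 0.35, JUN by -2.33 ± 0.19, TNFAIP3 by -1.95 ± 0.28 and NFKBIA by -1.73 ± 0.17. After ketoconazole CXCL8 averaged 10.78 with BSA and 11.57 with TNF for 1 h, against 10.09 with TNF in DMSO. NFKBIA averaged 11.48 and 12.68, against 12.87. A higher starting level and a ceiling of the array scale were not tested at 1 h. The DMSO control had 14 h in all and no BSA, while each drug control had BSA for 1 h, so time and carrier differed between the arms. The 73 genes were chosen by the DMSO response that enters the difference, which can favour smaller responses after any of the drugs. ANKRD18A, ZNF780A and ZNF92 had positive differences among all genes tested. Of 45 NF-kB targets 15 were lower and 0 higher (19 lower and 1 higher adjusted over the list alone, adjusted p = 2.2e-48, and adjusted p = 4e-11 with an estimated correlation). With nefazodone 10 of the 73 genes rose less and 0 more, CXCL8 by -2.09 ± 0.24 and JUN by -1.82 ± 0.20, while the gene of TNF itself, outside the 73, differed by 2.07 ± 0.35. With methotrexate CCL20 rose less and CXCL1, CXCL2 and SELE rose more, with CXCL2 at 2.59 ± 0.37. With diclofenac JUN and MAFF rose less, and with carbamazepine DDIT4, outside the 73, was the single gene called. The medians over the 73 genes were -0.16 with nefazodone, 0.01 with methotrexate, -0.12 with diclofenac and 0.11 with carbamazepine.

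At 6 h the genes among the 108 that rose less or more were 5 and 2 with diclofenac, 1 and 1 with carbamazepine, 2 and 2 with methotrexate, and 5 and 8 with nefazodone.

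Markers of other cell types, listed before the data were examined, were mostly near the bottom of the scale. The fibroblast genes COL1A1 and COL1A2 averaged 3.39 and 2.25, the leukocyte gene PTPRC 2.09 and the endothelial genes VWF and CDH5 2.46 and 2.37. ACTA2 (7.94), LYZ (11.99), KRT19 (9.21), EPCAM (10.41) and SOX9 (10.07) were abundant in all groups. PECAM1 rose with methotrexate and nefazodone against DMSO, PDGFRB and CD14 rose with methotrexate against DMSO and fell with TNF for 6 h after methotrexate, and with BSA for 6 h after ketoconazole KRT19 rose and SOX9 fell. The ACTB difference between 3 prime and 5 prime control probe sets was -0.19 with diclofenac, 0.13 with carbamazepine and -0.05 with methotrexate relative to DMSO (exact permutation p = 0.2, 0.4 and 0.886), and that of GAPDH lay between -0.03 and 0.05 with the 5 drugs.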
